A study of Populus alba x Populus glandulosa with 12 samples.

How the data were processed

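Leaf RNA of the hybrid poplar *Populus alba* × *P. glandulosa* was measured in 12 libraries: 4 from nontransgenic controls, 4 from line 2 and 4 from line 7 of plants that overexpress PagSUPa (OE), a C2H2-type zinc finger protein. Per the labels' protocols, cDNA was made with a SMARTer oligo(dT) method from total RNA, and libraries were amplified by rolling circles into DNA nanoballs. The labels give each group replicate numbers from 1 to 4 but do not say whether replicates came from separate plants. The p-values therefore measure the spread between these samples, which may be technical.

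The deposited table holds TPM (a transcript's share of all transcripts of a library, scaled to a fixed total), per its header and values: 34749 genes by 12 libraries, with nearly equal totals in all libraries (999989.2 to 999995.5). Cutadapt, FastQC and Salmon are named in the submitters' processing notes, without versions. Their settings, the genome build and the annotation release are not given in the sources used here. The table pairs the gene identifiers, which begin with Potri, with Arabidopsis loci (31436 genes), names (13350 genes) and descriptions. Gene names below are those of the paired Arabidopsis gene. No reference genome was used, so no coordinates are given. TPM keep no record of sequencing depth. The depth of each library is unknown, and no counting interval or detection floor is given. Because TPM are shares of a fixed total, a rise of some genes lowers the values of all others. Salmon divides reads between similar transcripts, so values of near-identical copies are uncertain. Reads of a transgene transcript and of a native gene of like sequence could not be told apart.

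From the TPM, log2(TPM + 1) was computed, and genes with a TPM of at least 1 in at least 4 of the 12 libraries were kept (24926 genes). A linear model with 3 groups was fitted to all 12 libraries with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, R 4.3.3). Contrasts were the mean of both OE lines against the control, each line against the control, and line 7 against line 2. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. All fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM. For the homologs of SUPERMAN relatives and of POK1 and POK2, exact two-sided permutation tests compared the groups over all splits of the libraries.

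Gene lists for leaf development, cell division, photosynthesis, hormones, cell walls, vascular and guard cell types, stress and defence were fixed before the data were examined, as were the main tests, the alternatives and the rule for named genes, with exceptions named here. A poplar gene belonged to a list if its paired Arabidopsis locus was listed or its description matched the list's pattern. Of 31 lists, 28 had at least 3 tested members. They were tested with camera (preset inter-gene correlation of 0.01), with camera using an estimated correlation, and with fry. Camera compares a list with all other genes. Fry asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. List p-values were adjusted over the 28 lists.

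The rule for named genes took the homologs of SUPERMAN and of POK1 and POK2. It also took the 10 largest rises and falls among annotated genes with a mean TPM of at least 5 that passed in all 3 contrasts with the control. From each list past the camera threshold, and from each cell division list, it took up to 4 members of smallest p. It allowed 5 genes each way for line 7 against line 2, where no gene passed. No gene in the table was named SUPERMAN or PagSUPa, and for that case the rule fixed beforehand was to report no gene as the overexpressed one. The homolog of ZFP11 belongs to the prepared list of SUPERMAN relatives and entered the named genes as 1 of the 10 largest rises. Its use as a check of the labels is a departure from that rule, chosen after its values were seen. The exact tests of the POK homologs, of which POK1 lay below the expression filter, and the list tests of line 7 against line 2 were also added after the data were examined.

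Alternatives were pseudocounts of 0.1 and 5, no expression filter, a mean TPM of at least 5, median ratio scaling, quantile normalization, the replicate number as a block, a fit of only the groups compared, eBayes without a trend, library weights, an adjusted p under 0.01, a log2 fold change of at least 1, and leaving out each library in turn. Leaving out the 2 libraries of lowest weight, and a test of gene families by shared description, were chosen after seeing the data. The overlap of the lines was compared with 100 simulations of unchanged groups that share the controls. The procedure was tested on simulated data with 24926 genes that varied independently of each other. In the contrast of both lines against control, 66% of 100 genes changed by 1 on the log2 scale and 94% of 100 genes changed by 2 were recovered, and 9 unchanged genes were called. In the contrast of line 7 against line 2 these shares were 58% and 95%, with 11 unchanged genes called. Camera called all 10 shifted lists and 0 of 10 unshifted lists, which does not test it on genes that vary together. Figures were drawn with matplotlib 3.10.9.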

Results

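Gene expression was profiled by RNA sequencing in leaves of the hybrid poplar *Populus alba* × *P. glandulosa*. The study compared nontransgenic control plants (4 libraries) with lines 2 and 7 of plants overexpressing PagSUPa (4 libraries each), and its title names PHRAGMOPLAST ORIENTING KINESIN as a target of PagSUPa in the control of cell division. Between 22710 and 24607 genes reached a TPM of 1 per library, and the 10 most abundant genes of each library held 9.62% to 16.2% of its TPM. Correlations of log2(TPM + 1) across tested genes ranged from 0.896 to 0.984 between libraries of a group, from 0.912 to 0.983 between the lines, and from 0.670 to 0.914 between OE and control libraries. The first principal component held 66.3% of the variance and separated all OE libraries from all controls. No libraries were identical. Control replicates 1 and 2 had the lowest library weights (0.318 and 0.514) and the highest median ratio factors (1.20 and 1.18). By correlation, replicate 1 lay apart from replicates 3 and 4 (0.936 and 0.934). Replicate 2 was as close to replicates 3 and 4 (0.966 and 0.972) as to replicate 1 (0.970).

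A homolog of SUPERMAN relatives was examined first, as a check of the labels that was chosen after its values were seen. The homolog of ZFP11, a zinc finger protein of the SUPERMAN family (Potri.002G041700), was at 0.028 ± 0.056 TPM (SD, n = 4) in controls, where 3 of 4 libraries were listed at 0. It reached 1435 ± 200 TPM in line 2 and 1394 ± 159 TPM in line 7 (SD, n = 4 each). Its log2 fold change in both lines was 10.42 (SE 0.11, limma adjusted p = 1.26e-13). An exact permutation test gave p = 0.00202 for 8 against 4 libraries and 0.0286 for each line, the smallest values these tests can give. The table names no gene PagSUPa or SUPERMAN, so whether this gene is the overexpressed one is not shown here. The 5 other listed relatives, 3 homologs of KNUCKLES and 1 each of RABBIT EARS and ZFP10, stayed at or below 0.348 TPM in every library and were not tested by limma.

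The kinesins named in the series title were lower in OE leaves. POK2 and POK1 are kinesins that guide the phragmoplast, the structure that builds the new cell wall, to the division site. The POK2 homolog (Potri.004G145800) fell from 2.78 ± 1.63 TPM in controls to 0.554 ± 0.225 TPM in line 2 and 0.664 ± 0.222 TPM in line 7 (SD, n = 4 each). Its log2 fold change was -1.14 (SE 0.23, limma adjusted p = 0.00169) in both lines, with -1.19 in line 2 (adjusted p = 0.0036) and -1.09 in line 7 (adjusted p = 0.00737). All 8 OE libraries lay below every control (exact permutation p = 0.00202). The POK1 homolog (Potri.010G153000) was at 0.748 ± 0.626 TPM in controls, 0.141 ± 0.098 TPM in line 2 and 0.149 ± 0.116 TPM in line 7 (SD, n = 4 each). It lay below the expression filter, and an exact permutation test over both lines gave a log2 difference of -0.55 (p = 0.00808). Against each line alone its exact p was 0.0571. Control replicates 1 and 2 had the highest values of both genes, at 4.84 and 3.32 TPM for POK2 and 1.58 and 0.882 TPM for POK1. The POK1 difference was -0.34 without control replicate 1 alone. Without both the POK2 change was -0.63 (adjusted p = 0.0182) and the POK1 difference -0.15 (exact p = 0.2). The POK2 change also depended on the pseudocount, with -1.91 at 0.1 and -0.45 at 5 (adjusted p = 0.00157 and 0.00336), as did that of POK1, with -1.58 and -0.15 (exact p = 0.00808 for both).

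**Figure D1:**
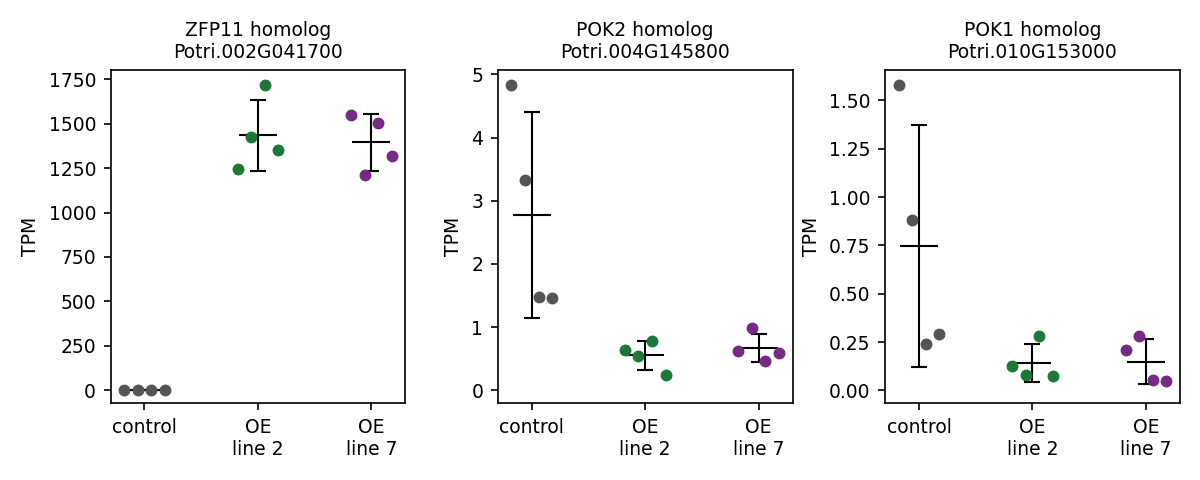
TPM of the ZFP11, POK2 and POK1 homologs in each library (points), with the mean and SD of each group (bar and whiskers, n = 4). The ZFP11 homolog was above 1210 TPM in every OE library and at most 0.112 TPM in the controls, and all 8 OE libraries lay below every control for POK2.

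Both OE lines together were compared with the control. The 10 largest rises were taken among annotated genes with a mean TPM of at least 5 that passed in all 3 contrasts with the control. They were in the ZFP11 homolog, 2 homologs of the cytochrome P450 CYP712A1, the berberine bridge family protein EDA28, extensin EXT1, MLP423, a cupredoxin, the peroxiredoxin PER1, the peroxidase RCI3 and a RING/U-box protein. Outside this set, 3 unannotated loci described further below rose by 8.07 to 9.7 on the log2 scale. EXT1 (Potri.005G190100), a structural cell wall protein, rose from 4.21 ± 3.06 TPM (SD, n = 4) to 345.2 ± 234.4 TPM (SD, n = 8), and later pairs of values give controls and OE libraries in the same form. EDA28 (Potri.001G463300) rose from 1.12 ± 0.85 to 159 ± 117 TPM, MLP423 (Potri.008G212500) from 1.05 ± 0.48 to 140 ± 128 TPM, the cupredoxin (Potri.005G079400) from 0.453 ± 0.473 to 73.5 ± 20.7 TPM and the RING/U-box protein (Potri.012G003900) from 0.906 ± 0.621 to 82.4 ± 38.7 TPM. The CYP712A1 homologs, PER1 and RCI3 were listed at 0 in 3 of 4 controls and averaged 80.7, 58.0, 241 and 67.6 TPM in OE leaves. For PER1, replicate 4 of line 7 was at 984 TPM and the other line 7 libraries at 3.37 to 149 TPM. The 2 CYP712A1 homologs had equal control values, and the division of reads between these copies is uncertain.

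Among the 10 largest falls by the same rule, the lipase LTL1 (Potri.019G024400) fell from 276 ± 82.7 to 2.68 ± 4.22 TPM, an HXXXD acyltransferase (Potri.010G208100) from 107 ± 36.0 to 1.60 ± 4.40 TPM, and a SAUR-like auxin-responsive gene (Potri.004G164400) from 69.8 ± 38.1 to 0.566 ± 0.614 TPM. Expansin EXP15 (Potri.013G060800), a wall-loosening protein, fell from 85.5 ± 20.8 to 4.81 ± 8.004 TPM, and the xylosidase BXL1 (Potri.008G108100) from 35.9 ± 14.6 to 0.628 ± 0.846 TPM. The proline-rich PRP4 homologs fell from 1252 ± 173 to 46.4 ± 44.5 TPM and from 870.5 ± 245 to 50 ± 49.2 TPM. Replicate 2 of line 7 was at 12.7 TPM for LTL1, 12.5 TPM for the acyltransferase and 2.60 TPM for BXL1, above every other line 7 library. HS1, a Pollen Ole e 1 protein and a pectin methylesterase inhibitor completed this set. Their log2 fold changes, -4.67 (SE 1.23), -4.66 (SE 0.97) and -4.51 (SE 0.81), passed with adjusted p = 0.008, 0.00227 and 0.000968. Across all 88 named genes, 84 had every OE library outside the range of the controls, which chance gives for 0.4% of genes, although most of these genes were picked for a small p or a large change. The exceptions were HS1, CENH3, CYCB2;4 and FZR3. HS1 (log2 fold change -5.025, adjusted p = 0.051) and PER1 (5.621, adjusted p = 0.0806) missed the threshold without control replicates 1 and 2. With all controls these changes were -4.67 and 5.65, so the lost calls do not show smaller effects.

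In all, 13980 of 24926 tested genes (56.1%) passed, 5511 higher and 8469 lower, and 2268 rose and 2713 fell by at least 1 on the log2 scale. The median log2 fold change of all genes was -0.133, and median ratio scaling moved it to -0.00655, with 7231 genes higher and 7093 lower. Of the 13980 genes, 12602 passed with the same sign under that scaling. The direction of small changes is therefore relative to this shift. The count was 7430 without control replicates 1 and 2 (3887 higher and 3543 lower), of which 7063 were in the original set with the same sign.

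Genes for cell division were examined in 6 lists. Of 29 tested phragmoplast and cytokinesis genes, 19 fell and 1 rose (median log2 fold change -0.855, camera adjusted p = 0.00399, but adjusted p = 0.813 with an estimated correlation). Among them 2 RhoGAP proteins with a PH domain, of a type that marks the division site, fell from 16.2 ± 4.72 to 5.08 ± 1.09 TPM (Potri.009G069700) and from 15.4 ± 5.55 to 5.33 ± 1.28 TPM (Potri.001G275200). The MAP kinase gene MPK4 (Potri.014G088500) rose from 5.95 ± 1.19 to 11.5 ± 1.34 TPM. Of 22 kinesins, 21 fell and 0 rose (median -1.22, camera adjusted p = 5.53e-06, but adjusted p = 0.813 with an estimated correlation). A kinesin motor protein (Potri.004G161100) fell from 42.9 ± 10.9 to 5.98 ± 2.48 TPM, KATD (Potri.005G021100) from 6.39 ± 2.18 to 1.10 ± 0.52 TPM and the calmodulin-binding KCBP (Potri.001G455300) from 14.5 ± 5.53 to 3.62 ± 1.34 TPM. The kinesin and phragmoplast lists share 3 genes. Of 38 genes for the G1/S step and DNA replication, 21 fell and 4 rose (median -0.683, camera adjusted p = 0.0171, but adjusted p = 0.813 with an estimated correlation). The D-type cyclins CYCD1;1 (Potri.010G095200) and CYCD3 (Potri.002G123000), which promote entry into the cell cycle, fell from 21.8 ± 2.56 to 6.54 ± 1.57 TPM and from 15.6 ± 4.96 to 5.22 ± 1.44 TPM. The retinoblastoma-related RB (Potri.001G031400), which restrains that entry, fell from 15.8 ± 4.97 to 7.59 ± 1.03 TPM.

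Of 24 mitotic cyclins, B-type CDKs and spindle genes, 16 fell and 2 rose (median -0.88, camera adjusted p = 0.0495, but adjusted p = 0.813 with an estimated correlation). This call was lost in 13 of 22 alternatives, among them fry (adjusted p = 0.0807). CYCB2;4 (Potri.009G165800) fell from 2.32 ± 1.47 to 0.686 ± 0.352 TPM and the centromeric histone CENH3 (Potri.014G096400) from 2.33 ± 1.12 to 1.09 ± 0.14 TPM, whereas the 2 homologs of the CDK subunit CKS2 rose from 34.3 ± 3.03 to 49.6 ± 7.82 TPM and from 25.1 ± 2.50 to 35.3 ± 6.25 TPM. Of 57 core histone genes, 17 fell and 3 rose, and the list did not pass (adjusted p = 0.469). Under median ratio scaling 13 fell and 9 rose, and 10 or 11 fell without control replicate 1 or 2 (adjusted p = 0.817 and 0.196). HTA12 (Potri.006G082300), an H2A histone, fell from 387 ± 49.8 to 253 ± 29.9 TPM. The histone list also took in, by its description as a histone methyltransferase of the SET7/9 family, a gene that is not a histone (Potri.003G085000). It fell from 14.4 ± 4.34 to 4.10 ± 1.87 TPM. Of 12 CDK inhibitors and endocycle genes, 3 rose and 4 fell (adjusted p = 0.944). The CDK inhibitors ICK5 (Potri.009G103600) and ICK2 (Potri.007G042300) rose from 5.28 ± 1.11 to 10.6 ± 2.76 TPM and from 17.5 ± 5.79 to 31.6 ± 6.58 TPM, and the cell cycle switch genes CCS52A1 (Potri.003G119500) and FZR3 (Potri.010G202100) fell.

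Adjusted over the list alone, 23 phragmoplast, 21 kinesin, 24 G1/S, 18 mitotic, 13 histone and 4 CDK inhibitor genes fell, and 1, 0, 4, 2, 3 and 3 rose. For the phragmoplast, kinesin and G1/S lists fry gave adjusted p = 0.0153, 0.00362 and 0.0193. The mitotic call was also lost without control replicate 1 (adjusted p = 0.125, 2 genes lower), control replicate 2 (0.0679, 3 genes lower), replicates 1, 2 or 4 of line 2 (0.06, 0.0639 and 0.0853) or replicates 3 or 4 of line 7 (0.0812 and 0.0612). The G1/S call was lost without control replicate 1 (adjusted p = 0.062, 12 genes lower), and 12 of its genes fell without control replicate 2. Without both of these controls the lower genes numbered 4 in the phragmoplast list (camera adjusted p = 0.0165), 11 among kinesins (5.97e-06), 7 in the G1/S list (0.156) and 0 in the mitotic list (0.321). The CKS2 homologs, CENH3, CYCB2;4, CCS52A1, FZR3 and ICK2 then missed the threshold (adjusted p from 0.054 to 0.25). At a mean TPM of at least 5 the phragmoplast call was lost (adjusted p = 0.193) and the mitotic median was 0.108 (adjusted p = 0.579), and the mitotic call was lost at pseudocounts of 0.1 and 5 (0.0518 and 0.0532).

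More regulators of leaf growth and leaf polarity fell than rose. Of 45 leaf growth regulators, 30 fell and 2 rose (median -0.64, camera adjusted p = 0.000467, but adjusted p = 0.813 with an estimated correlation). The homologs of BIG BROTHER, a ubiquitin ligase that limits organ size, fell from 6.49 ± 2.75 to 0.565 ± 0.344 TPM (Potri.009G062100) and from 7.86 ± 1.55 to 3.43 ± 0.88 TPM (Potri.003G204500). The TCP4 homolog, listed as MEE35 (Potri.013G119400), of a family that ends cell proliferation in leaves, fell from 34.5 ± 4.31 to 9.998 ± 2.98 TPM, and GRF8 (Potri.001G082700), of a family that promotes proliferation, from 5.25 ± 1.99 to 1.02 ± 0.52 TPM. Of 28 leaf polarity genes, 19 fell and 0 rose (median -0.742, camera adjusted p = 0.000608, but adjusted p = 0.813 with an estimated correlation). The YABBY gene AFO (Potri.003G112800) fell from 34.8 ± 7.24 to 3.58 ± 2.64 TPM, KAN2 (Potri.003G096300) from 3.41 ± 0.72 to 0.632 ± 0.219 TPM and AS1 (Potri.017G112300) from 66.1 ± 17.03 to 19.1 ± 7.66 TPM. AFO and KAN2 act on the lower leaf side and AS1 acts with upper-side genes. Of 13 stomatal lineage and guard cell genes, 7 fell and 0 rose (median -0.574, camera adjusted p = 0.0435, but adjusted p = 0.813 with an estimated correlation). They included MYB60 (Potri.019G045900), from 21.2 ± 1.15 to 2.63 ± 1.45 TPM, and FAMA, listed as FMA (Potri.017G054500), from 7.38 ± 1.32 to 3.70 ± 1.05 TPM. Of 21 epidermis, cuticle and trichome genes, 11 fell and 4 rose (adjusted p = 0.243).

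Adjusted over the list alone, 31 growth, 20 polarity, 7 stomatal and 11 epidermis genes fell, and 2, 0, 0 and 4 rose. Fry gave adjusted p = 0.00362, 0.0056 and 0.00362 for the growth, polarity and stomatal lists. The stomatal call was also lost without control replicate 1 (adjusted p = 0.0725) or replicate 3 of line 7 (0.0521). With control replicates 1 and 2 left out, 11 growth genes, 7 polarity genes and 5 stomatal genes fell (camera adjusted p = 0.0013, 0.0123 and 0.097). The stomatal call was also lost at a pseudocount of 0.1 (0.0518).

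More xylem and phloem genes fell than rose. Of 36 secondary wall and xylem genes, 30 fell and 2 rose (median -1.72, camera adjusted p = 3.23e-06, but adjusted p = 0.813 with an estimated correlation). The NAC master regulator ANAC043 (Potri.011G153300) fell from 11.5 ± 1.48 to 3.04 ± 1.09 TPM, MYB46 (Potri.001G258700) from 1.88 ± 0.37 to 0.308 ± 0.150 TPM, the xylan synthesis gene IRX9 (Potri.016G086400) from 11.5 ± 2.36 to 2.44 ± 1.23 TPM and the laccase LAC17 (Potri.011G120200) from 10.6 ± 3.33 to 1.41 ± 1.46 TPM. Of 22 phloem genes, 18 fell and 0 rose (median -1.08, camera adjusted p = 0.000592, but adjusted p = 0.813 with an estimated correlation). The 2 homologs of APL, a regulator of phloem identity, fell from 23.1 ± 2.15 to 13.5 ± 2.13 TPM and from 15.01 ± 1.61 to 9.69 ± 1.27 TPM. Of 35 lignin and phenylpropanoid genes, 16 rose and 3 fell (median 0.70, camera adjusted p = 0.00317, but adjusted p = 0.813 with an estimated correlation). Cinnamate 4-hydroxylase C4H (Potri.018G146100) rose from 2.17 ± 0.43 to 10.3 ± 2.82 TPM, and 2 homologs of the acyltransferase HCT rose from 3.80 ± 1.30 to 15.1 ± 3.77 TPM and from 2.28 ± 0.79 to 9.54 ± 2.56 TPM. The ferulate 5-hydroxylase homolog CYP84A1 (Potri.005G117500), needed for syringyl lignin, fell from 15.3 ± 2.32 to 1.08 ± 0.78 TPM. Of 31 flavonoid and anthocyanin genes, 15 rose and 8 fell (median 1.19, camera adjusted p = 0.0299, but adjusted p = 0.813 with an estimated correlation). Only 3 of 8 OE libraries had a list mean of log2(TPM + 1) above the controls (4.15 to 4.70), replicate 3 of line 2 (5.70) and replicates 1 and 2 of line 7 (6.68 and 6.76), and the others lay at 4.16 to 4.54. Anthocyanidin synthase ANS (Potri.001G113100) rose from 6.54 ± 1.97 to 205 ± 209 TPM, a chalcone isomerase (Potri.010G213000) from 58.2 ± 7.69 to 213 ± 55.04 TPM and the flavonol regulator MYB12 (Potri.003G144300) from 5.21 ± 1.21 to 20.6 ± 7.30 TPM.

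Adjusted over the list alone, 30 xylem and 22 phloem genes fell, 16 lignin and 15 flavonoid genes rose, and 2 xylem and 0 phloem genes rose while 3 lignin and 8 flavonoid genes fell. Fry gave adjusted p = 0.00362, 0.0064, 0.0064 and 0.213 for the xylem, phloem, lignin and flavonoid lists. The flavonoid call was also lost under median ratio scaling (adjusted p = 0.124), quantile normalization (0.0948), a mean TPM of at least 5 (0.125) and without replicate 2 of line 7 (0.0811), and without control replicate 1 only 8 of its genes rose (0.0443). Without control replicate 2, 8 phloem genes fell (0.00075). With both of control replicates 1 and 2 left out, 22 xylem and 6 phloem genes fell and 9 lignin and 5 flavonoid genes rose (camera adjusted p = 1.69e-06, 0.000388, 0.0165 and 0.0992).

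More genes of the photosynthetic apparatus fell than rose. Of 103 genes for photosystems, light harvesting and Rubisco, 59 fell and 11 rose (median -0.576, camera adjusted p = 0.000981, but adjusted p = 0.813 with an estimated correlation). The light-harvesting gene LHCB2 (Potri.014G165100) fell from 7444 ± 777 to 2260 ± 494 TPM and the photosystem I subunit PSAF (Potri.003G148900) from 1116 ± 110 to 234.1 ± 79.0 TPM. In contrast, 2 homologs of ELIP, a protein induced by excess light, rose from 1.34 ± 0.67 to 12.2 ± 4.55 TPM and from 60.2 ± 15.2 to 412 ± 212 TPM. Under median ratio scaling 43 genes of this list fell and 11 rose. Of 61 cytosolic ribosomal protein genes, 31 rose and 1 fell (median 0.394, camera adjusted p = 1.97e-07, but adjusted p = 0.813 with an estimated correlation), and 49 rose under median ratio scaling. An L18e/L15 family gene (Potri.010G045800) rose from 216 ± 15.8 to 436 ± 63.5 TPM. Adjusted over the list alone, 61 photosynthesis genes fell and 11 rose, and 30 ribosomal genes rose and 1 fell. Fry gave adjusted p = 0.015 and 0.0219 for these lists. Without control replicates 1 and 2, 33 photosynthesis genes fell and 6 rose (camera adjusted p = 2.05e-05), and 38 ribosomal genes rose (4.51e-11). Without control replicate 3 or 4 the ribosomal rises numbered 20 or 19 (2.05e-06 and 1.55e-06).

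More genes of the defence and ethylene lists rose than fell, which did not extend to every gene family described further below. Of 90 WRKY factors and defence genes, 45 rose and 13 fell (median 0.899, camera adjusted p = 3.23e-06, but adjusted p = 0.813 with an estimated correlation). EDS1 (Potri.015G069600) and SAG101 (Potri.T004600), partners in immune signalling, rose from 1.11 ± 0.61 to 11.6 ± 1.28 TPM and from 0.182 ± 0.241 to 3.24 ± 0.83 TPM. WRKY57 (Potri.010G160100) rose from 0.948 ± 0.413 to 14.2 ± 4.16 TPM and WRKY30 (Potri.012G031700) from 0.260 ± 0.060 to 3.61 ± 1.04 TPM. Of 39 genes for ethylene synthesis and ERF factors, 18 rose and 1 fell (median 0.719, camera adjusted p = 0.000188, but adjusted p = 0.813 with an estimated correlation). ERF1 (Potri.011G061700) rose from 0.461 ± 0.381 to 11.3 ± 4.63 TPM and ERF-1 (Potri.003G150700) from 25.4 ± 9.73 to 127 ± 44.5 TPM, while the gene that fell was the ethylene-forming enzyme ACO4 (Potri.014G159000), from 1827 ± 323 to 706 ± 101 TPM. EDF3 (Potri.T036200) was listed at 0 in 3 of 4 controls and averaged 9.21 TPM in OE leaves. Adjusted over the list alone, 46 defence and 18 ethylene genes rose and 15 and 1 fell. Fry gave adjusted p = 0.00362 and 0.011 for these lists. Without control replicates 1 and 2, 28 defence and 10 ethylene genes were higher (camera adjusted p = 0.000159 and 0.0145).

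The other lists did not pass with camera. For hormones, 24 of 117 auxin genes rose and 48 fell (adjusted p = 0.358), 9 of 26 cytokinin genes rose and 6 fell (0.221), 5 of 32 gibberellin genes rose and 13 fell (0.469), and 4 of 20 brassinosteroid genes rose and 10 fell (0.171). Fry, which looks only within a list, gave adjusted p = 0.0388 for auxin, 0.0253 for gibberellin and 0.00362 for brassinosteroid. Of 42 jasmonate genes 6 rose and 7 fell (0.469), and of 65 abscisic acid and drought genes 23 rose and 19 fell (0.165). Of 42 expansins and xyloglucan endotransglucosylases 8 rose and 17 fell (0.469). Of 111 heat shock proteins and chaperones 21 rose and 36 fell (0.903), of 29 circadian clock genes 2 rose and 8 fell (0.903), and of 13 senescence genes 1 rose and 5 fell (0.91). The cytokinin and circadian clock lists share 6 genes. The heat shock median was -0.0548 while camera's direction was up, and the senescence median was -0.322 while its mean was 0.00462. Under median ratio scaling the heat shock and circadian medians changed sign, to 0.0861 and 0.0607, as did the heat shock median without control replicate 1 or 2 (0.0149 and 0.0245). Adjusted over the list alone, 25 auxin, 9 cytokinin, 5 gibberellin, 4 brassinosteroid, 4 jasmonate, 23 abscisic acid, 8 expansin, 21 heat shock, 2 clock and 1 senescence genes rose, and 49, 6, 13, 11, 7, 20, 17, 36, 6 and 5 fell. The meristem and floral organ lists had 1 tested member each, CLV1 (log2 fold change 0.889, SE 0.27, adjusted p = 0.0163) and AP3 (0.377, SE 0.19, adjusted p = 0.115).

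**Figure D2:**
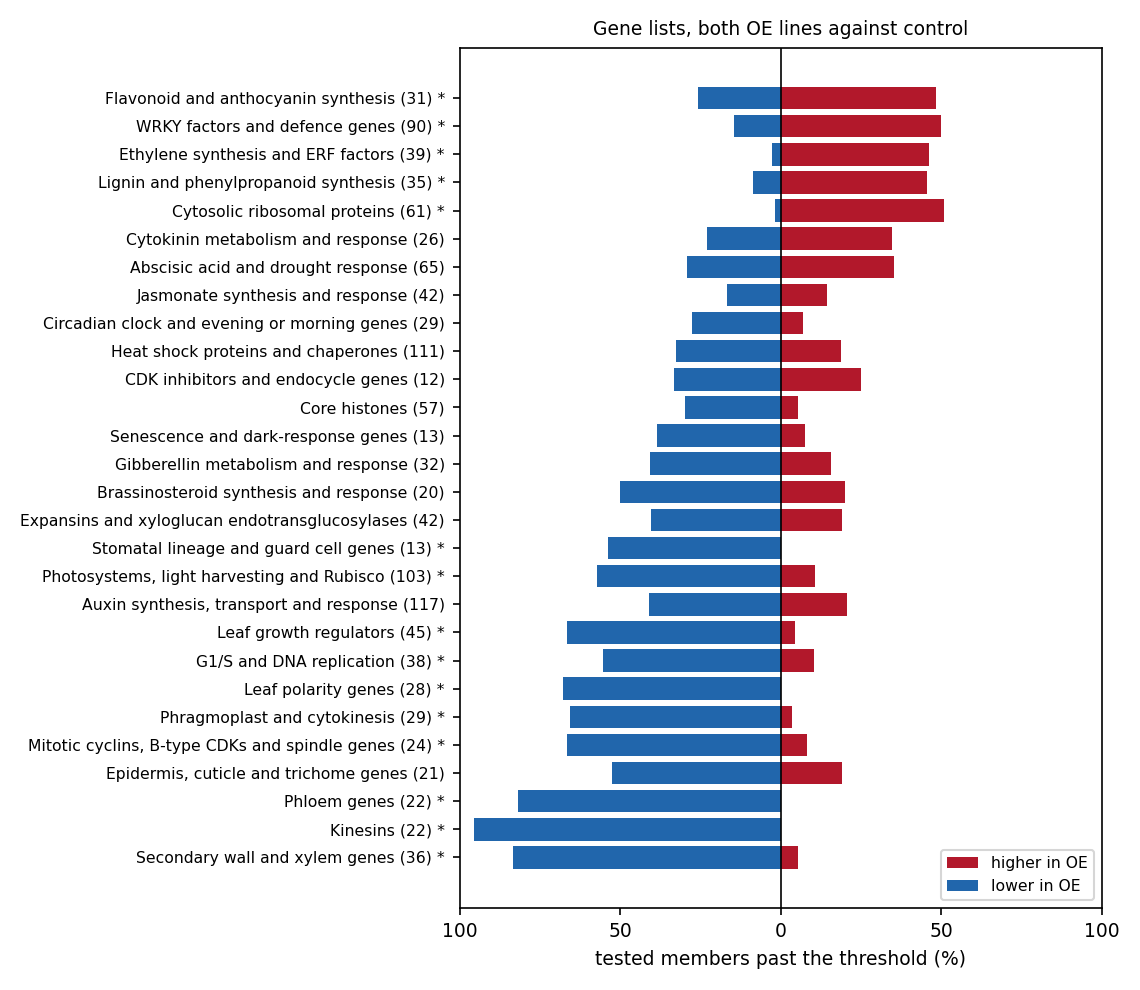
Share of tested members (%) of each of the 28 lists that rose (to the right) or fell (to the left) in both OE lines against control, with the number of tested members in parentheses and an asterisk for the 15 lists past the camera threshold, whose calls were lost with an estimated correlation. Lists are sorted by median log2 fold change, from secondary wall and xylem genes (-1.72) to flavonoid genes (1.19), and the heat shock and circadian medians change sign under median ratio scaling.

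**Figure D3:**
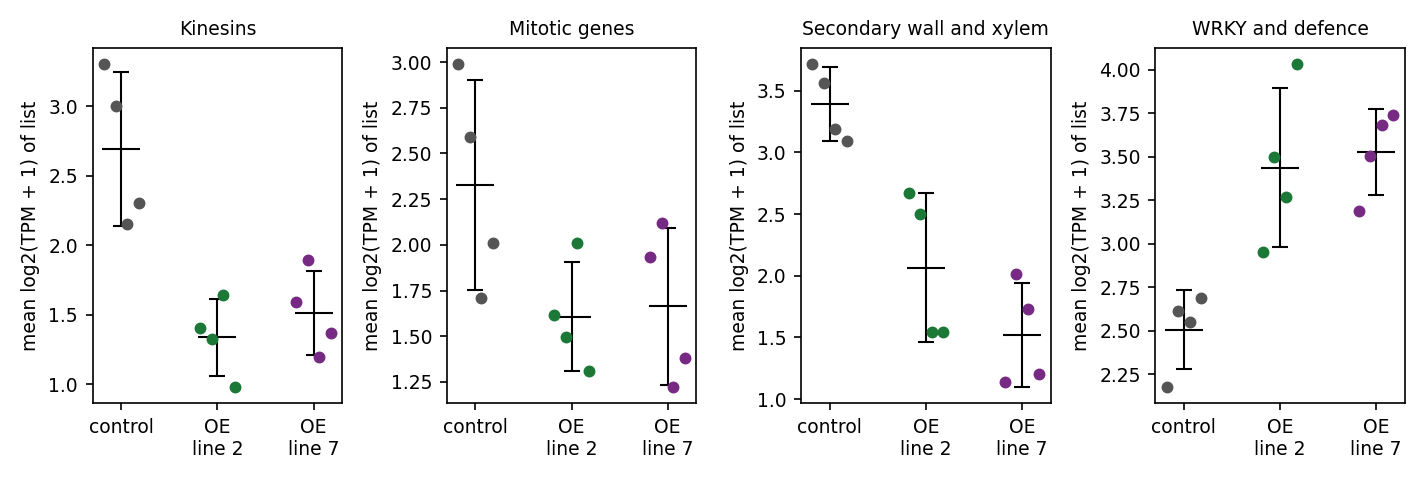
Mean log2(TPM + 1) over the tested members of 4 lists in each library (points), with the mean and SD of each group (bar and whiskers, n = 4). The vertical axes do not start at 0. OE libraries lie below all controls for kinesins and for secondary wall and xylem genes and above all controls for WRKY and defence genes, and they overlap the controls for mitotic genes.

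Each line was also compared with the control alone. In line 2, 12756 genes passed, 4685 higher and 8071 lower, and in line 7, 10910 passed, 4716 higher and 6194 lower. Under median ratio scaling the lines had 6664 higher and 6388 lower, and 5894 higher and 5739 lower. The lines shared 10182 genes with the same direction, 4181 higher and 6001 lower, and 0 genes passed in opposite directions. Under median ratio scaling these were 5539 and 5306. Independent lists of these sizes would share 886 and 2006 genes. Across genes, which are not independent replicates, the effects of the lines had a correlation of 0.979 and a covariance of 0.926. Because the lines share their controls, simulated unchanged groups gave a mean correlation of 0.455 (from -0.648 to 0.951), a mean covariance of 0.0372 (at most 0.193) and at most 0 genes called in both. The covariance exceeded the simulated mean by 0.888. With different controls for each line, over 6 splits of the controls, the correlation was 0.866 to 0.953 and the covariance 0.851 to 0.914. Signs were equal for 93.8% of genes, against 66.0% in simulations and at least 79.5% with split controls. With control replicates 1 and 2 left out, 6885 genes passed in line 2 (3277 higher and 3608 lower), and the excess of lower genes turned in line 7 (5013 genes, 3058 higher and 1955 lower) and among shared genes (4606, with 2739 higher and 1867 lower). Camera called the same 15 lists in line 7 as in both lines and 12 of them in line 2. None was called with an estimated correlation (smallest adjusted p = 0.794 in line 7 and 0.881 in line 2). The mitotic (adjusted p = 0.0976), stomatal (0.0787) and flavonoid lists (0.0976) did not pass in line 2, where 7 flavonoid genes rose and 9 fell, against 15 and 7 in line 7. Of the mitotic genes 13 fell in line 2 and 5 in line 7, or 15 and 0 when adjusted over the list alone. Their medians were close, at -0.926 and -0.839, and 0 of 24 passed between the lines (camera adjusted p = 0.321).

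**Figure D4:**
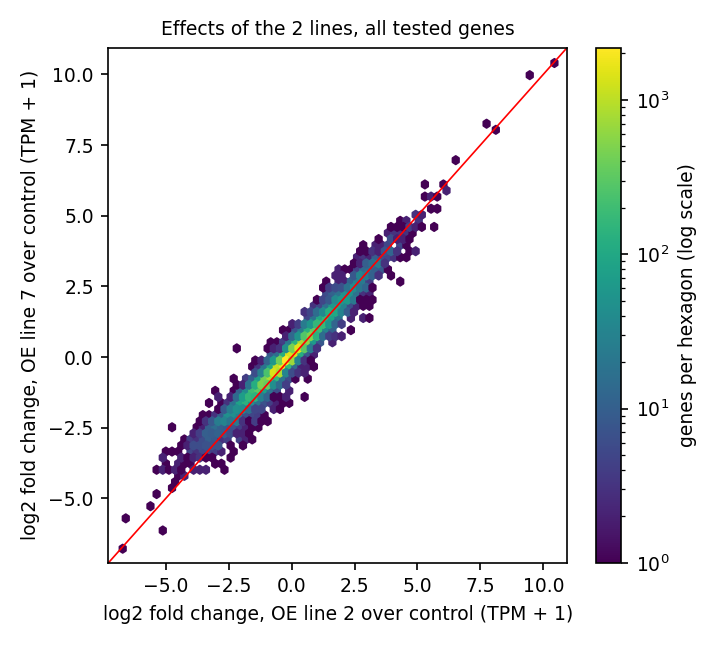
Log2 fold change of each of 24926 tested genes in OE line 2 (horizontal) and OE line 7 (vertical) against the shared controls, as the number of genes per hexagon on a log colour scale. The red line marks equal effects; genes lie along it, with a correlation across genes of 0.979.

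The lines were then compared with each other. By limma, 0 genes passed between line 7 and line 2 (smallest adjusted p = 0.661), and 418 genes (1.68%) had an unadjusted p under 0.05. The latter count ran from 281 to 874 with 1 library left out, and was 1994 with library weights, 669 with no filter and 271 at a mean TPM of at least 5. The median SE of a log2 difference was 0.182. The number of genes passing was 0 in each alternative fit that was run. Among the lists, camera called secondary wall and xylem genes lower in line 7 (median difference -0.617, adjusted p = 1.67e-32), and leaf growth regulators (0.201, adjusted p = 0.00634) and flavonoid genes (0.754, adjusted p = 0.000372) higher. With an estimated correlation these calls were lost (adjusted p = 0.301, 0.952 and 0.952), and fry gave an adjusted p of 0.894 for each. The list means overlapped between the lines. For flavonoid genes, replicates 1 and 2 of line 7 stood at 6.68 and 6.76 and its replicates 3 and 4 at 4.16 and 4.19, below every line 2 library (4.22 to 5.70). No member of these lists passed over all genes, and adjusted over the list alone 1 xylem gene was lower in line 7.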

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

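The tests of other splits of the libraries, and of gene lists between the lines, were chosen after the counts of genes were seen. Of 357 groups of 4 libraries examined for a library far from the other 3, 23 had one, where chance gives about 18. The value given for each is the gap to the nearest library divided by the range of the group.

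Replicate 2 of line 7 stood above the other line 7 libraries for LTL1 (ratio 0.935, 12.7 TPM), Potri.010G208100 (0.995, 12.5 TPM against at most 0.063), HS1 (0.951, 309.6 TPM), BXL1 (0.903, 2.60 TPM), ACO4 (0.84, 880 TPM), LAC17 (0.956, 1.39 TPM) and HT1 (0.906, 20.9 TPM). In each case its value was on the side of the controls. Replicate 4 of line 7 stood high for PER1 (0.852, 984 TPM against at most 149).

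In line 2, replicate 4 stood low for EXP15 (0.915, 0.797 TPM) and Potri.003G085000 (0.835, 2.28 TPM) and high for CYP75B1 (0.867, 2.43 TPM). Replicate 3 of line 2 stood high for CENH3 (0.914, 1.27 TPM) and MYB12 (0.835, 30.1 TPM).

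Among controls, replicate 1 stood high for Potri.009G019300 (0.851, 1067 TPM against at most 410) and HTA12 (0.924, 461 TPM against at most 365). Replicate 3 stood low for the mean of the CDK inhibitor list (0.915) and of the flavonoid list (0.948). For ZFP11, PER1, RCI3, EDF3 and both CYP712A1 homologs the ratio was 1 because a single control, at most 0.196 TPM, was above 0.

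The effects of the lines differed by camera for leaf growth regulators (adjusted p = 0.00634), secondary wall and xylem genes (1.67e-32) and flavonoid genes (0.000372). None of these differences passed with an estimated correlation (adjusted p = 0.952, 0.301 and 0.952), and that of flavonoid genes rested on replicates 1 and 2 of line 7.

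Other splits of the same libraries were counted for each comparison. For both lines against control, 1 of 100 splits drawn called as many genes, the real split with 13980, and the highest other gave 6485. For line 2 against control it was 1 of 35 (12756 against at most 0 in the others), for line 7 against control 1 of 35 (10910 against at most 1), and for genes changed in both lines 1 of 100 (10182 against at most 2). For these 4 results no other split examined called as many genes, which argues against chance. Splits that mix OE and control libraries also widen the spread within groups, so their low counts do not measure chance alone. For line 7 against line 2 the count of splits tests nothing, since 0 genes were called and all 35 splits must give as many. A single other split of the 8 OE libraries called 1896 genes. It set replicates 1 and 3 of line 2 and replicates 1 and 2 of line 7 against the rest. The split matched the sign of the score on the main axis of spread within groups, which is described further below. The libraries named here scored 0.157 to 0.383 and the rest -0.468 to -0.0296. On the same axis control replicates 1 and 2 scored 0.282 and 0.0957, and replicates 3 and 4 scored -0.198 and -0.179. The axis did not follow the line. Replicate 1 scored above 0 and replicate 4 below 0 in every group, while replicates 2 and 3 went both ways.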

How the results depend on the processing

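Leaving out control replicates 1 and 2 was chosen after seeing the data; the other alternatives were fixed before. Counts changed with the expression filter and thresholds by their construction. Requiring a mean TPM of at least 5 left 9019 genes changed in both lines against control, 8240 in line 2, 7087 in line 7 and 6609 shared by the lines. An adjusted p under 0.01 left 9270, 7653 and 5410. A log2 fold change of at least 1 left 4981, 5204 and 4345. Without control replicates 1 and 2 the counts were 7430, 6885 and 5013, with 4606 shared, in a fit with fewer samples, and the POK1 difference was -0.1477 (exact p = 0.2). With an estimated correlation 0 gene lists passed. The mitotic list median turned to 0.108 at a mean TPM of at least 5, a filter that removes its low members. Leaving out each library in turn gave 11206 to 14000 genes for both lines, 10234 to 12689 for line 2, 7929 to 11316 for line 7, 7412 to 10192 shared, 0 between the lines, and 12 to 15 lists; each minimum came without control replicate 1. POK2 then ranged from -1.313 to -0.8993 in both lines, -1.364 to -0.95 in line 2 and -1.263 to -0.8487 in line 7, POK1 from -0.692 to -0.339, and ZFP11 from 10.38 to 10.46, 10.35 to 10.5 and 10.35 to 10.47.

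Pseudocounts, no filter, median ratio and quantile scaling, eBayes without a trend, library weights and fits of only the groups compared kept each of these counts within 1.5 times and the calls of ZFP11 and POK2, though pseudocounts of 0.1 and 5 by their construction moved POK2 to -1.906 and -0.4489 and POK1 to -1.581 and -0.1538. For both lines against control, a fit of only the groups compared already holds all 12 libraries. Of 1875 other values of named genes, 9 missed the threshold, all without control replicates 1 and 2, and 1866 kept direction and call. Most of these genes were picked from the same data for a small p or a large change, so kept calls were likely. Of 616 values for gene lists, which include lists that camera did not call, 572 kept direction and call, 40 were weaker, 3 stronger and 1 reversed. With the replicate number as a block, 13745 genes changed in both lines, 12527 in line 2, 10763 in line 7 and 0 between the lines, and the flavonoid list lost its call (adjusted p = 0.0712). The labels give no shared origin for a replicate number. Of 12 same-number pairs, 9 had correlated deviations over 0.1 (range -0.472 to 0.415), and 5 of 12 libraries correlated best with their own number. Pairs of replicate 1 lay at 0.236 to 0.321 and those of replicate 3 at -0.472 to 0.302. A partial pairing by number therefore stays open. TPM do not show depth, so its effect on low genes such as POK1 is unknown.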

Other observations

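Of the tests below, only that of the 10 most abundant genes is recorded as chosen before its result was seen. Those of the kinesin, phragmoplast, G1/S and photosystem list means had a first bound but were judged by a criterion set after the result. The change of criterion turned 3 verdicts. By the bound first set, a remainder within 0.3 of 0, those of phragmoplast (-0.187) and G1/S genes (-0.17) met what a common shift predicts, and that of photosystem genes (-0.309) went against it, though by less than its error of 0.1. Gene families were formed after seeing the data, as genes that share a description. Of 270 families with at least 10 tested members, camera called 63, 36 higher and 27 lower in OE leaves, and 0 with an estimated correlation (smallest adjusted p = 0.885). Families of receptor kinases went both ways. Of 34 genes described as receptor-like protein kinase 1, 30 rose and 3 fell (median log2 fold change 1.15, camera adjusted p = 2.38e-11), as did 9 of 10 wall-associated kinases with 0 lower (8.86e-06), 14 of 18 malectin receptor kinases with 1 lower (1.35e-05) and 10 of 11 PR5-like receptor kinases with 0 lower (5.04e-05). Families with leucine-rich repeats were themselves divided. Of 33 genes described as leucine-rich receptor-like protein kinases, 26 fell and 4 rose (median -0.974, 0.0109). Of 21 described as leucine-rich repeat receptor-like protein kinases, 11 rose and 4 fell (median 0.582, 0.0263). Families not called included 134 leucine-rich repeat protein kinases, of which 70 fell and 23 rose (0.123). Another was 31 leucine-rich repeat transmembrane protein kinases, with 11 higher and 11 lower (0.588). The FERONIA homolog Potri.017G096400 rose from 21.3 to 59.2 TPM (log2 fold change 1.43, SE 0.10). All 14 genes matched to glutathione S-transferase tau 7, detoxifying enzymes, rose (median 2.4, 9.82e-10), with Potri.008G174900 at 4.45 TPM in controls and 175 TPM in OE leaves. Called families of resistance proteins also differed in direction: 57 of 111 NB-ARC proteins fell and 13 rose (0.0223), while 19 of 41 TIR-NBS-LRR proteins rose and 7 fell (0.0321). Further families of these classes were not called. Of 26 genes described as putative TIR-NBS-LRR proteins 5 rose and 3 fell (0.383), and of 46 LRR and NB-ARC proteins 18 fell and 3 rose (0.28). Of 24 pathogenesis-related thaumatin proteins 17 fell and 1 rose (median -1.27, 0.0223). Of 18 dirigent-like resistance-responsive proteins 10 rose and 4 fell (median 0.786, 0.0255). The 64 integrase-type DNA-binding proteins were not called, with 10 higher and 12 lower (median 0.0819, 0.399).

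Among lower families, 32 of 44 pectin lyase-like proteins fell and 3 rose (median -1.2, 0.000366), and 28 of 43 O-fucosyltransferases fell and 2 rose (median -0.758, 0.000273). Some of the most abundant transcripts shifted too. The metallothionein MT3 (Potri.001G400100) rose from 10780 ± 8810 to 36780 ± 14000 TPM (SD, n = 4 and 8, limma adjusted p = 0.00414), and a light-harvesting LHB1B1 homolog (Potri.005G239200) fell from 18530 ± 1060 to 9386 ± 1470 TPM (adjusted p = 0.00149). The 2 MT2A homologs and Potri.001G400200 also rose (limma adjusted p = 0.000362, 0.00394 and 0.00203). A second LHB1B1 homolog (Potri.005G239300), at 13530 ± 1180 TPM in controls and 10340 ± 1450 TPM in OE leaves, missed the threshold (adjusted p = 0.093). Both Rubisco small subunit genes among the 10 most abundant missed it too (adjusted p = 0.299 and 0.289), as did RCA (0.456) and PSAD-2 (0.0959).

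The first pattern is the lower level of division and kinesin genes. A shift of TPM by abundant genes is argued against: under median ratio scaling the median of these genes lay -0.779 from that of all genes. A different stage of the sampled leaves stays open. The labels give no leaf position or stage, and the meaning of the tag L6, shared by all column headers, is not given. The main axis of spread within groups (41.3% of it) correlated 0.612 in size with the OE effect across genes, which are not independent replicates. The next axes gave 0.0314 and 0.0979. Taking out what the difference in the mitotic list (-0.689) predicts from the slope within groups left -0.675 of -1.27 for kinesins and -0.187 of -0.701 for phragmoplast genes without kinesins. This argues against a shift along that slope as the full account of these lists. The exact permutation p, with the slope held fixed, was 0.00202 for each, the smallest possible. It was the same with the reverse slope, which left -0.639 and -0.181. For phragmoplast genes this verdict rests on the criterion set after the result. A stage difference that moves kinesin and mitotic genes in another ratio was not tested. For G1/S genes -0.17 of -0.706 was left (exact p = 0.0283, but -0.115 and 0.147 with the reverse slope). For photosystem genes -0.309 of -0.438 was left (exact p = 0.0182, but with the reverse slope the sign turned, to 0.334 with 0.248). A common shift along that slope therefore stays open for G1/S and photosystem genes, and leaf stage stays open for all of these lists. A specific effect of the transgene on kinesins remains a hypothesis.

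The second pattern is the excess of genes called lower over genes called higher, which rests largely on control replicates 1 and 2: without them 47.7% of called genes were lower in both lines, 52.4% in line 2 and 39% in line 7, and the median of all genes in both lines was -0.0178. Under median ratio scaling 49.5% of called genes were lower, but that scaling centres all genes, so the balance decides nothing about the cause. The 10 most abundant genes held 9.97% ± 1.61 of TPM in controls and 12.8% ± 2.37 in OE libraries (SD, n = 4 and 8). Leaving them out moved the median of all genes from -0.133 to -0.095, a value that does not decide whether they are the source. No biological explanation was tested.

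The third pattern is a set of 3 unannotated loci, chosen after their values were seen. Potri.002G055566 was at most 5.20 TPM in controls and between 32.1 and 21894 TPM in OE libraries (limma adjusted p = 0.000367), Potri.002G055533 at most 0.468 and between 4.97 and 2277 TPM, and Potri.005G206901 at most 3.34 and between 23.8 and 5509 TPM. The ratio of any pair varied at most 4.59-fold over the OE libraries while the levels varied at least 231-fold, but as the loci and the bound were chosen after the values were seen, and 8 of 23510 genes, 2 of them from this set, correlated over 0.95 with Potri.002G055566, a shared RNA source stays undecided. The range of Potri.002G055566 was 482 times that of the ZFP11 homolog, which varied 1.42-fold, but as that gene is not shown to be the transgene, reads of the transgene transcript stay open as a source. What the loci encode was not examined, as no genome was used here.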
